A study of Homo sapiens with 15 samples.

How the data were processed

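Poly(A) RNA of 15 libraries of the TF-1 cell line was sequenced in 5 groups of 3, taken from the genotype in the sample labels. Per the labels' protocols, cells grew in RPMI-1640 with 10% FBS and 1% penicillin and streptomycin, Parental cells with 2 ng/ml GM-CSF and base-edited cells without it, and libraries were made from 0.1 to 1 ug of RNA with a poly(A) selection module and a directional library kit. The authors deposited one table of TPM values, transcript abundances scaled for length and to a fixed library total, with one column per library and gene symbols as row names. The submitters' processing notes name STAR 2.7.3, HTSeq, RSEM and DESeq2 and the build hg38, with no role for each. The annotation release, the strand setting and any filter are not given in the sources used here. Each column summed to about 1000000, and the smallest value above 0 was 0.01. TPM divides reads by transcript length and by the library's total, so a change in a few abundant genes moves all others, and it keeps no read number. The depth per library, and the precision that depth gives, are therefore unknown.

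The table held 63568 rows. Values of rows with one symbol were summed, which left 56624 symbols, 2985 of them from more than 1 row. Of symbols that a spreadsheet had turned into dates, 6 rows that could belong to more than 1 gene were left out. Genes with at least 1 TPM in at least 3 libraries were tested, which gave 14881, of which 224 came from more than 1 row. GENCODE release 29, used for coordinates and gene types, matched 13067 of them (87.8%).

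Values were taken as log2(TPM + 1), with a pseudocount of 1, and fitted with limma 3.58.1 in R 4.3.3 with one mean per group over all 15 libraries and an intensity trend for the variance. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1. Each mutant and the mean of the 4 was compared with Parental, IDH1R132H with the mean of the IDH2 mutants, and the IDH2 mutants with each other. Gene lists written beforehand, 44 in number, were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. A list needed 5 tested members, which left 43, and p-values were adjusted over these within a comparison. Groups, tests, thresholds, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named IDH1 and IDH2, the 6 largest rises and 6 largest falls per comparison among changed genes with at least 10 TPM in the higher group and groups that did not overlap, the 3 changed members with the smallest adjusted p of each list that passed, and 10 genes each way for changes in all 4 mutants. Other members of a fixed list could be named beside its count.

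The procedure was tested on simulated data for IDH1R132H against Parental over 14881 genes. It recovered 65 of 67 genes changed by log2 1.5, 66 of 67 changed by 2 and 66 of 66 changed by 3, with 10 false calls, and made 0 calls where nothing was changed. The changed genes were all raised and stood at about 10 TPM or more in Parental, with noise drawn independently for each gene. Recovery of falls and of genes at lower levels was not tested. Alternatives were another pseudocount, other filters, median-ratio scaling, quantile normalisation, rescaling without globin and mitochondrially encoded genes, fits of only the compared libraries, without the variance trend or with library weights, the replicate number as a block, and leaving out each library in turn. Leaving out symbols on more than 1 row, and leaving out Parental replicate 2 with IDH2R140W replicate 3, were added after the data were seen. Symbols listed at 0 in a group were given no fold change. A few members of the gene lists are counted with their list and are not reported here by name.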

Results

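RNA was sequenced from TF-1, a human erythroleukaemia cell line that grows in response to cytokines such as GM-CSF, and from isogenic TF-1 lines carrying a base-edited mutation of IDH1 or IDH2. Base editing converts single bases in the genome without cutting both DNA strands. The 15 libraries fell into 5 groups of 3, which were Parental, IDH1R132H, IDH2R140Q, IDH2R140W and IDH2R172K. The series asked how the edited IDH mutations alter the transcriptome. Parental cells were grown with 2 ng/ml GM-CSF and the edited cells without it, so genotype and medium changed together in every comparison with Parental, whereas the 4 edited lines shared their medium. Expression was given in TPM, a transcript abundance scaled for length and to a fixed library total, which keeps no read depth, so the depth of each library is unknown and no counting interval can be given. Between 12796 and 13792 gene symbols reached 1 TPM in a library. Across genes, which are not independent, libraries of one group correlated with Pearson's r between 0.974 and 0.990, and each library lay closest to another of its own group. Ribosomal protein genes held 20.5% of the TPM in Parental replicate 2 and 21.4% in IDH2R140W replicate 3, against 16.3% to 18.0% in the other libraries of those groups.

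Levels are mean TPM ± SD (n = 3 libraries), and differences are on the log2(TPM + 1) scale, which understates changes of genes at low level. A gene changed where its limma adjusted p was under 0.05 and its level differed at least 2-fold. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Exact tests of 3 libraries against 3 cannot go below p = 0.10, and every adjusted p therefore rests on a spread shared across groups and genes. For each gene named among the largest rises or falls, all 3 libraries of one group lay outside the range of the other, a separation that chance gives to 10% of genes. The median gene was shifted against Parental by 0.16 in IDH1R132H, 0.23 in IDH2R140Q, 0.03 in IDH2R140W and 0.13 in IDH2R172K, and medians of gene lists are given relative to these shifts.

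The edited genes themselves were compared with Parental. IDH1, which encodes the cytosolic NADP-dependent isocitrate dehydrogenase (ENSG00000138413, hg38 chromosome 2, 208236227 to 208266074, minus strand), stood at 70.3 ± 3.81 TPM in Parental. It fell to 36.8 ± 2.23 in IDH1R132H (log2 difference −0.92, limma adjusted p = 3.31e-06), to 34.6 ± 3.19 in IDH2R140W (adjusted p = 3.31e-06) and to 37.7 ± 2.80 in IDH2R172K (−0.88, 5.79e-06). In IDH2R140Q IDH1 was 60.3 ± 5.87 and did not pass (−0.22, adjusted p = 0.0704), but it passed without IDH2R140Q replicate 3 (0.0310) and after median-ratio scaling (−0.48, 0.000848), within a range of 0.000848 to 0.212 over the alternatives. IDH2, which encodes the mitochondrial enzyme (ENSG00000182054, chromosome 15, 90083045 to 90102504, minus strand), stood at 52.7 ± 3.18 in Parental. It rose to 74.7 ± 1.03 in IDH2R140Q (0.50, adjusted p = 0.000242) and fell to 31.8 ± 1.72 in IDH2R172K (−0.71, 1.06e-05). The rise in IDH2R140Q was 0.24 after median-ratio scaling (adjusted p = 0.0191, range over the alternatives 1.31e-05 to 0.0191) and 0.34 after quantile normalisation. IDH2 was 52.3 ± 4.22 in IDH1R132H (−0.01, adjusted p = 0.900) and 45.4 ± 3.32 in IDH2R140W (−0.21, 0.0745), where it passed without Parental replicate 2 (0.0495). After median-ratio scaling both IDH2 differences passed, at −0.21 with adjusted p = 0.0324 in IDH1R132H (range over the alternatives 0.0324 to 1) and at −0.26 with 0.0167 in IDH2R140W (0.00622 to 0.232). The IDH2 difference in IDH1R132H was above 0 without Parental replicate 3 (0.03) and without IDH1R132H replicate 3 (0.04). Of these differences only the fall of IDH1 in IDH2R140W reached 2-fold, and it was −0.93 without IDH2R140W replicate 3 and −0.97 without Parental replicate 3. After median-ratio scaling the falls of IDH1 in IDH1R132H and IDH2R172K also passed 2-fold, at −1.11 and −1.04, as did that in IDH1R132H after quantile normalisation, at −1.08. TPM does not show which allele was transcribed, so the edits were not checked here.

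**Figure D1:**
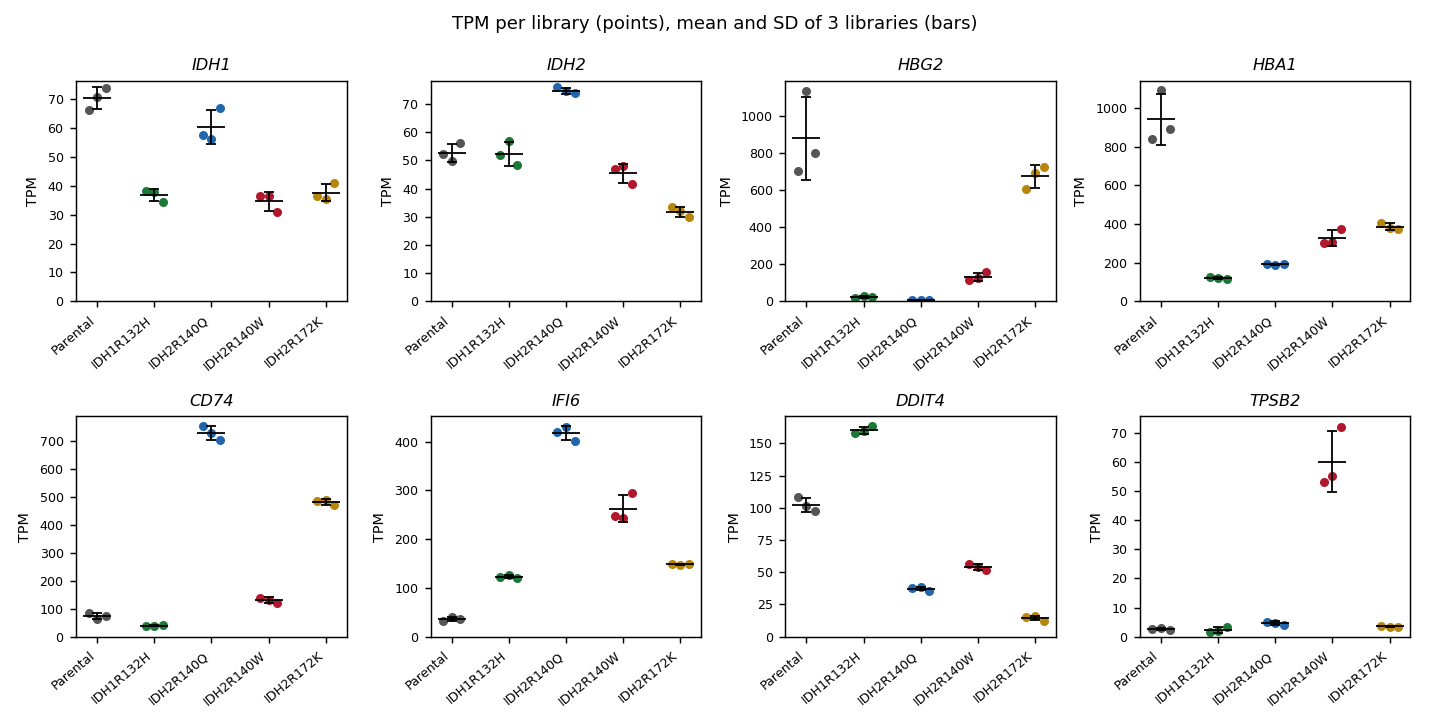
TPM (linear y axis, one panel per gene) of IDH1, IDH2, HBG2, HBA1, CD74, IFI6, DDIT4 and TPSB2 in the 5 groups on the x axis, with each of the 3 libraries as a point and the mean and SD as a bar. HBG2 stood at 880.4 ± 225 in Parental and 6.07 ± 1.23 in IDH2R140Q, and CD74 at 74.9 ± 9.93 and 727 ± 24.7.

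In IDH1R132H cells, haemoglobin and other red cell transcripts were lower than in Parental. HBG2, a fetal gamma globin chain, fell from 880.4 ± 225 to 24.0 ± 5.75 TPM (log2 difference −5.14, adjusted p = 2.76e-10), and HBB, the adult beta chain, fell from 69.0 ± 8.31 to 1.31 ± 0.875 (−4.99, 7.96e-10). Of 9 globins 8 fell and 1 did not pass, with a median of −3.81 relative to all genes (camera adjusted p = 1.23e-11, adjusted p = 0.0486 with an estimated correlation). Among 13 genes of haem synthesis 4 fell, including ALAS2, the erythroid form of the enzyme that starts the pathway (camera adjusted p = 0.000167, adjusted p = 0.0787 with an estimated correlation). Of 27 erythroid regulators and membrane genes 7 fell, 1 rose and 19 did not pass (0.000202, adjusted p = 0.168 with an estimated correlation), and after quantile normalisation 11 fell and none rose. Carbonic anhydrase CA1, abundant in red cells, fell from 135 ± 12.2 to 10.4 ± 0.619. Megakaryocyte genes rose, with 9 of 14 higher and 5 not passing (0.000244, adjusted p = 0.227 with an estimated correlation). SELP, the platelet adhesion molecule P-selectin, rose from 2.00 ± 0.546 to 24.0 ± 2.44, and RAB27B, a GTPase of platelet granule release, from 1.497 ± 0.4996 to 30.4 ± 1.02.

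Further gene groups moved in IDH1R132H. Of 23 NF-kB and inflammatory cytokine genes 9 rose, 1 fell and 13 did not pass (camera adjusted p = 0.00958, adjusted p = 0.263 with an estimated correlation). Over the alternatives the adjusted p of that list ran from 2.14e-05 to 0.0995, the highest with a minimum of 5 TPM, and after quantile normalisation 5 members rose. CD44, a receptor for hyaluronan, rose from 195 ± 39.2 to 1187 ± 31.1, and the chemokine CCL2 from 2.63 ± 0.936 to 23.6 ± 4.14. Of 21 STAT5 targets, genes that GM-CSF and related cytokines induce, 5 fell and 1 rose (0.00310, adjusted p = 0.570 with an estimated correlation), and ID1, an inhibitor of basic helix-loop-helix factors, fell from 477 ± 72.0 to 112 ± 3.61. Of 27 genes of ATF4 and the amino acid response 3 rose and none fell (0.00958, adjusted p = 0.555 with an estimated correlation). These were the pseudokinase TRIB3 (90.6 ± 5.54 against 39.96 ± 2.52, under 2-fold after median-ratio scaling at 0.97), the stress factor DDIT3 (23.5 ± 0.386 against 8.29 ± 1.48) and ATF3 (13.8 ± 2.96 against 2.24 ± 0.958). HLA class II presentation fell as a list with 2 of 10 members lower, or 4 after median-ratio scaling or quantile normalisation (6.1e-06, adjusted p = 0.0156 with an estimated correlation), among them IFI30, a lysosomal thiol reductase, from 83.2 ± 2.56 to 19.6 ± 0.891. The 13 mitochondrially encoded genes fell as a list with none changed alone (median −0.61, 3.8e-05, adjusted p = 0.515 with an estimated correlation), and 1 fell after median-ratio scaling or without Parental replicate 2. Ribosomal protein genes fell as a list with 1 of 69 lower (median −0.44; camera adjusted p = 3.16e-15, adjusted p = 0.555 with an estimated correlation), where their share of TPM was 14.7% to 14.99% against 16.3%, 20.5% and 17.3% in Parental. The gene was RPS7 (968 ± 13.9 against 2030 ± 284), under 2-fold without Parental replicate 2 (−0.95) and after quantile normalisation (−0.90). The interferon response had 14 of 42 members higher, and the list did not pass (camera adjusted p = 0.0914).

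The largest rises in IDH1R132H included MS4A2, the beta chain of the high-affinity IgE receptor, at 33.6 ± 0.664 against 0.413 ± 0.171 TPM (4.62, adjusted p = 1.09e-10), and CTSG, the granule protease cathepsin G, at 32.5 ± 0.701 against 0.467 ± 0.486 (4.57, 7.72e-10). BMPER, a secreted regulator of BMP signals, MMP9, a matrix metalloproteinase, and the transcribed pseudogene TSSC2 rose by 4.84, 4.29 and 4.70. The chemokine CCL7 was listed at 0 in the 3 Parental libraries and at 21.67, 24.65 and 22.57 in IDH1R132H. KCNH2, a potassium channel, fell from 102 ± 12.997 to 3.83 ± 0.561, and FAM178B from 57.2 ± 9.39 to 2.53 ± 0.743. MIR1182 was listed at 0 in the 3 IDH1R132H libraries and at 31.87, 30.82 and 20.99 in Parental. It is a short microRNA gene (chromosome 1, 231019828 to 231019924), and how far poly(A) selection keeps such transcripts is unknown. Its values therefore need not measure the microRNA. MMP9 and TRIB3 lie on chromosome 20, whose protein-coding genes stood 0.35 above all others in this comparison. ID1 lies on it too, in a run of 25 genes (24949230 to 32809356) with a median of −0.54.

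By limma 1612 of 14881 genes changed in IDH1R132H, 1152 higher and 460 lower (71.5% higher). After median-ratio scaling 818 were higher and 676 lower (54.8% higher). For all lists named in the comparison of IDH1R132H with Parental, the count adjusted over the list alone was that over all genes. By camera 17 of 43 lists passed, 2 of them also with an estimated correlation.

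IDH2R140Q cells had the lowest HBG2 and the highest IFI6 and CD74 of the 5 groups. HBG2 stood at 6.07 ± 1.23 TPM (log2 difference −6.95, limma adjusted p = 1.14e-11), and 8 of 9 globins fell with 1 not passing (median −3.69; camera adjusted p = 2.81e-16, adjusted p = 0.01002 with an estimated correlation). Of 42 interferon response genes 26 rose and 16 did not pass (median 0.93; 6.64e-12, adjusted p = 0.01002 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein, rose from 36.4 ± 3.43 to 417 ± 14.4, and IFI44L from 0.123 ± 0.180 to 18.9 ± 2.81. OAS1, which makes 2-5A in response to double-stranded RNA, was listed at 0 in the 3 Parental libraries and at 21.57, 17.42 and 19.70 in IDH2R140Q. Of 10 genes of HLA class II presentation 8 rose and 2 did not pass (median 2.40; 0.000329, adjusted p = 0.0204 with an estimated correlation). CD74, the invariant chain, rose from 74.9 ± 9.93 to 727 ± 24.7 (3.27, adjusted p = 5.44e-12), and CIITA, the class II transactivator, from 2.59 ± 0.987 to 22.3 ± 1.08. Most HLA symbols stand on several rows that were summed, and without such symbols the class II list did not pass (adjusted p = 0.255, the highest of a range from 1.04e-06 over the alternatives).

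Red cell genes fell in IDH2R140Q beyond the globins, with 8 of 27 erythroid regulators and membrane genes lower (camera adjusted p = 2.04e-05, adjusted p = 0.0626 with an estimated correlation). Carbonic anhydrase CA2 fell from 59.1 ± 2.59 to 2.82 ± 1.03. Of 14 megakaryocyte genes 10 rose and 2 fell (0.000200, adjusted p = 0.169 with an estimated correlation), and PPBP, a chemokine of platelet granules, rose from 0.267 ± 0.275 to 38.2 ± 0.927. The HOXA and HOXB list fell with 2 of 18 members lower, or 6 after median-ratio scaling or quantile normalisation (6.82e-06, adjusted p = 0.01002 with an estimated correlation), where the 2 were HOXA4 (5.64 ± 1.26 against 13.7 ± 0.312) and HOXA5 (5.15 ± 1.02 against 12.3 ± 1.90). STAT5 targets fell with 3 of 21 lower (0.00140, adjusted p = 0.432 with an estimated correlation), and these were ID1, the cytokine LIF and SOCS3, a feedback inhibitor of cytokine signals. The STAT5 list did not pass in IDH2R140W (camera adjusted p = 0.802) or IDH2R172K (0.0882), which also grew without GM-CSF. Ribosomal protein genes fell as a list with 2 of 69 lower (median −0.66; 4.41e-28, adjusted p = 0.209 with an estimated correlation), and their share of TPM was 13.4% to 13.5% in IDH2R140Q, 16.3% and 17.3% in Parental replicates 1 and 3 and 20.5% in Parental replicate 2. The 2 were RPL7 (1214 ± 10.1 against 2609 ± 261, under 2-fold after quantile normalisation) and RPS20 (1088 ± 26.5 against 2559.7 ± 394). HLA class I presentation rose with 3 of 11 higher (0.00268, adjusted p = 0.0463 with an estimated correlation), with a range of 0.000191 to 0.131 over the alternatives, the highest without symbols on several rows. The mitochondrially encoded list rose (0.0132, adjusted p = 0.574 with an estimated correlation), with a range of 0.000114 to 0.0656 over the alternatives, the highest after median-ratio scaling. Mitochondrial transcripts held 6.91% of the TPM in IDH2R140Q replicate 2 against 5.65% and 5.68% in replicates 1 and 3.

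EMC10, a subunit of the endoplasmic reticulum membrane protein complex (chromosome 19, 50476400 to 50490870), was nearly lost from IDH2R140Q at 0.050 ± 0.0866 TPM against 32.4 ± 3.59 in Parental (−4.99, adjusted p = 1.19e-12). FGF13, an intracellular fibroblast growth factor homologue, fell from 43.3 ± 3.45 to 0.0167 ± 0.0289. The largest rises also held MMP9, LTBP1, a binding protein of latent TGF-beta, and F13A1, the A chain of coagulation factor XIII (62.6 ± 2.69 against 3.65 ± 1.13). Protein-coding genes of chromosome 20, where MMP9 lies, stood 0.49 above all others in IDH2R140Q, whereas the run of 25 genes around ID1 stood at −0.60. Those of chromosome 10 stood at −0.41.

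By limma 1492 genes changed in IDH2R140Q, 1125 higher and 367 lower (75.4% higher), and after median-ratio scaling 719 were higher and 577 lower (55.5% higher). The lists named in this comparison had the same counts when adjusted over the list alone. By camera 19 of 43 lists passed, 5 of them also with an estimated correlation.

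IDH2R140W cells showed higher mast cell and basophil transcripts, higher interferon-induced transcripts and lower cholesterol synthesis transcripts than Parental. TPSB2 and TPSAB1, the mast cell tryptases, rose from 2.77 ± 0.346 to 60.1 ± 10.4 TPM (log2 difference 4.01, limma adjusted p = 3.66e-09) and from 0.733 ± 0.302 to 17.5 ± 0.739. FCER1A, the alpha chain of the high-affinity IgE receptor, rose from 77.6 ± 7.91 to 319 ± 13.7. The tryptases are near-identical copies, so reads may be split among them. Of 16 eosinophil, basophil and mast cell genes 9 rose, 1 fell and 6 did not pass (median 1.46; camera adjusted p = 6.86e-05, adjusted p = 0.0144 with an estimated correlation). Of 42 interferon response genes 16 rose and none fell (median 0.74; 2.19e-12, adjusted p = 0.0142 with an estimated correlation), with IFI6 at 262 ± 27.8 against 36.4 ± 3.43 and IFI27 at 16.9 ± 3.36 against 0.317 ± 0.287. OAS1, listed at 0 in Parental, was listed at 10.74, 10.83 and 7.75. Cholesterol synthesis fell as a list (median −0.77; 4.25e-12, adjusted p = 0.0144 with an estimated correlation) with 3 of 23 members lower, and 6 after median-ratio scaling or without Parental replicate 2 and 5 without IDH2R140W replicate 2. Among the 3 were HMGCS1, which makes HMG-CoA (65.3 ± 9.40 against 153 ± 22.5), and mevalonate kinase, MVK (7.76 ± 0.376 against 22.5 ± 3.10). Cholesterol synthesis also passed as lower in IDH2R172K (camera adjusted p = 0.000804), though not with an estimated correlation. It did not pass in IDH1R132H (0.956) or IDH2R140Q (0.0991).

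Globins fell in IDH2R140W with 6 of 9 lower, 1 higher and 2 not passing (camera adjusted p = 3.81e-05, adjusted p = 0.116 with an estimated correlation). HBZ, the embryonic zeta chain, fell from 105 ± 11.3 to 5.15 ± 2.10, whereas HBD, the delta chain, rose from 57.2 ± 4.16 to 198 ± 22.2. Haematopoietic cytokines rose with 5 of 12 higher (2.66e-06, adjusted p = 0.0667 with an estimated correlation), among them oncostatin M, OSM (36.5 ± 3.32 against 8.94 ± 0.833), and ANGPT2, a ligand of the endothelial receptor TIE2 (64.0 ± 14.2 against 18.9 ± 3.86). NF-kB and inflammatory cytokine genes rose with 6 of 23 higher, or 3 with a minimum of 5 TPM (0.000155, adjusted p = 0.0882 with an estimated correlation), and CCL2 rose from 2.63 ± 0.936 to 70.7 ± 3.33. The list of 37 mitosis genes fell with none changed alone (4.99e-07, adjusted p = 0.117 with an estimated correlation). HLA class II presentation rose with 4 of 10 higher and 1 lower (0.0273, adjusted p = 0.116 with an estimated correlation). That call was lost without IDH2R140W replicate 3 (0.0758), and the direction reversed without symbols on several rows (0.949), within a range of 0.00276 to 0.949 over the alternatives. HLA class I presentation rose with 2 of 11 higher (0.000594, adjusted p = 0.0260 with an estimated correlation), with a range of 5.16e-05 to 0.239, the highest without such symbols.

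The largest falls in IDH2R140W were those of MS4A4A, a membrane protein of macrophages and mast cells (2.58 ± 1.29 against 208 ± 18.0), FAM178B, NFE4, a factor of fetal globin expression (0.530 ± 0.335 against 29.2 ± 4.61), HBZ, the RNA-binding protein IGF2BP1 (0.663 ± 0.376 against 28.4 ± 13.9) and GGT5, a gamma-glutamyltransferase. By limma 711 genes changed, 399 higher and 312 lower (56.1% higher). Adjusted over the list alone, the counts of the lists named did not differ, and 17 of 43 lists passed by camera, 4 of them also with an estimated correlation.

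IDH2R172K cells had lower transcripts of the amino acid response and of NRF2 targets than Parental. ASNS, asparagine synthetase, fell from 39.3 ± 0.671 to 9.37 ± 0.462 TPM (log2 difference −1.96, limma adjusted p = 1.12e-09), and DDIT4, a stress-induced inhibitor of mTORC1, from 102 ± 5.55 to 14.6 ± 1.86 (−2.74, 4.77e-11). PHGDH, which starts serine synthesis, fell from 101 ± 3.28 to 46.0 ± 2.74. Of 27 genes of ATF4 and the amino acid response 10 fell and 17 did not pass (median −0.77; camera adjusted p = 2.43e-10, adjusted p = 0.0666 with an estimated correlation). Of 21 NRF2 targets 5 fell, 1 rose and 15 did not pass (median −0.44; 3.69e-05, adjusted p = 0.0197 with an estimated correlation). AKR1C1, an aldo-keto reductase, fell from 115 ± 5.48 to 28.0 ± 3.17, malic enzyme ME1 from 82.6 ± 1.92 to 30.8 ± 1.74, and the quinone reductase NQO1 from 56.1 ± 2.60 to 24.9 ± 1.82.

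HLA class II presentation rose in IDH2R172K with 8 of 10 higher and 1 lower (median 1.39; camera adjusted p = 0.000348, adjusted p = 0.0348 with an estimated correlation), and CD74 stood at 481 ± 9.39 TPM against 74.9 ± 9.93. Over the alternatives the adjusted p of the class II list ran from 1.88e-07 to 0.144, the highest without symbols on several rows. HLA class I presentation rose with 3 of 11 higher (0.00275, adjusted p = 0.0666 with an estimated correlation), with a range of 0.000247 to 0.0744, the highest without such symbols. Of 42 interferon response genes 12 rose and 1 fell (0.00381, adjusted p = 0.192 with an estimated correlation), and OAS1 was listed at 6.44, 5.51 and 3.80 against 0 in Parental. Adhesion and integrin genes rose with 8 of 27 higher (9.31e-05, adjusted p = 0.302 with an estimated correlation), among them CDH5, the cadherin of endothelial junctions (24.5 ± 0.0404 against 0.747 ± 0.212). Megakaryocyte genes rose with 6 of 14 higher (0.00439, adjusted p = 0.302 with an estimated correlation), and SELP stood at 47.7 ± 5.43. Only 2 of 9 globins fell, the alpha chains HBA1 and HBA2 (median −0.76; 0.00103, adjusted p = 0.241 with an estimated correlation), and HBG2 stood at 676 ± 62.4. Ribosomal protein genes fell as a list with 2 of 69 lower (median −0.39; 5.06e-14, adjusted p = 0.436 with an estimated correlation), where their share of TPM was 14.4% to 14.8% against 16.3%, 20.5% and 17.3% in Parental. The 2 were RPS6 (1540.2 ± 17.3 against 4396 ± 824) and RPS27A, which was under 2-fold without Parental replicate 2 (−0.96) and after quantile normalisation (−0.95), and after median-ratio scaling 4 fell.

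The largest rise in IDH2R172K was that of HDC, the histidine decarboxylase that makes histamine, from 1.29 ± 0.580 to 109 ± 3.18 TPM (5.63, adjusted p = 3.55e-10). HSH2D, an adaptor of haematopoietic cells, rose from 1.89 ± 0.794 to 92.3 ± 1.497, TMPRSS15, the intestinal protease enteropeptidase, from 0.803 ± 0.287 to 49.9 ± 1.13, and CTSG from 0.467 ± 0.486 to 57.7 ± 2.21. BMPER and the long noncoding RNA LINC00922 rose by 4.65 and 4.36. The largest falls included CA2 (1.01 ± 0.493 against 59.1 ± 2.59), the secreted protein CYTL1 (0.610 ± 0.176 against 32.2 ± 3.90) and MGST1, a microsomal glutathione transferase (6.55 ± 1.17 against 101 ± 16.5). CA2 lies on chromosome 8, whose protein-coding genes stood at −0.37 relative to all others in IDH2R172K, and the run of 25 genes around it at −0.54. By limma 1386 genes changed, 946 higher and 440 lower (68.3% higher), and after median-ratio scaling 756 were higher and 625 lower (54.7% higher). Adjusted over the list alone, these lists had the counts given, and 13 of 43 lists passed by camera, 2 of them also with an estimated correlation.

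**Figure D2:**
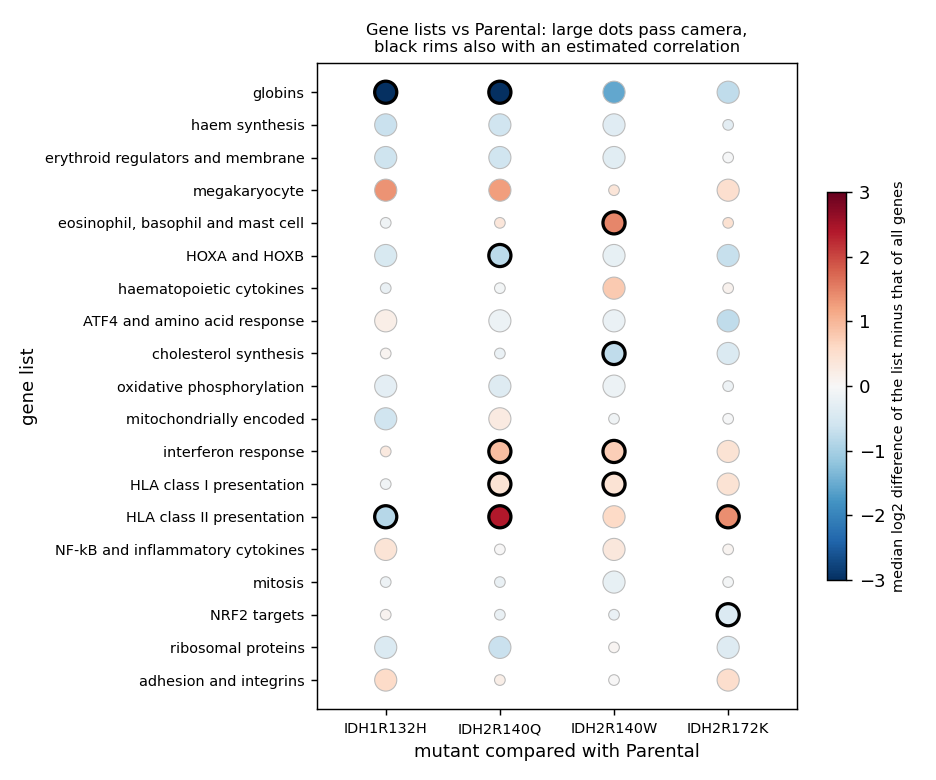
Fixed gene lists (y axis) in the 4 mutants against Parental (x axis), where the colour gives the median log2 difference of a list minus that of all genes, large dots mark lists that passed camera with the preset correlation and black rims those that also passed with an estimated one. The globin median was −3.81 in IDH1R132H and −0.76 in IDH2R172K.

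Some changes were shared by all 4 mutants. CTSG rose from 0.467 ± 0.486 TPM in Parental to between 11.003 ± 1.98 in IDH2R140Q and 57.7 ± 2.21 in IDH2R172K, and SERPINE2, an inhibitor of serine proteases, from 3.10 ± 0.359 to between 25.2 ± 4.56 in IDH1R132H and 53.9 ± 0.655 in IDH2R140Q. FCER1A rose from 77.6 ± 7.91 to between 248 ± 3.57 in IDH2R172K and 637 ± 40.6 in IDH2R140Q, and IFI6 from 36.4 ± 3.43 to between 123 ± 2.37 in IDH1R132H and 417 ± 14.4 in IDH2R140Q. The adrenergic receptor ADRA2A, the orphan receptor GPR141, the zinc finger protein ZNF91, C19orf77, the actin monooxygenase MICAL2 and osteopontin, SPP1, also rose in all 4. FAM178B fell from 57.2 ± 9.39 to at most 2.53 ± 0.743, CA2 from 59.1 ± 2.59 to at most 7.73 ± 1.42, and FAM83A from 68.7 ± 6.33 to at most 16.99 ± 1.56. The noncoding RNA UCA1, the phosphatase ACPP, GGT5, FGF13, the adhesion protein AMIGO2, the ribonuclease RNASE1 and the glycosyltransferase GALNT14 also fell in all 4.

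By limma 118 genes were higher and 72 lower in all 4 mutants (62.1% higher, and 51.9% after median-ratio scaling). Independent lists of these sizes would share 0.148 and 0.00703 genes. In 50 simulated sets of unchanged groups set against the same controls the overlap was 0 in every set. There a mean of only 0.12 genes changed in at least 1 comparison, so that 0 was fixed beforehand. It gives no chance value for lists as long as the real ones. The mean correlation of log2 differences between mutants was 0.559, against 0.507 (0.483 to 0.533) in the simulated sets, and the mean covariance was 0.219 against 0.0249. The 3 controls cannot be divided with 2 libraries in each part, so part of the excess may come from the shared controls. All 4 mutants also grew without the GM-CSF that Parental cells had. In the changes shared by all 4, medium and genotype therefore cannot be told apart. In the mean of the 4 mutants 835 genes changed, 593 higher and 242 lower (71.0% higher, and 54.6% after median-ratio scaling). In that mean 8 of 9 globins fell (median −2.39; camera adjusted p = 8.36e-11, adjusted p = 0.0429 with an estimated correlation), 16 of 42 interferon response genes rose (median 0.74; 5.63e-07, adjusted p = 0.0429 with an estimated correlation) and HOXA and HOXB genes fell as a list with none changed alone (median −0.52; 0.000442, adjusted p = 0.0429 with an estimated correlation). The mean hides differences between mutants, since only 2 of 9 globins fell in IDH2R172K. The interferon response list did not pass in IDH1R132H (camera adjusted p = 0.0914). Of the HOXA and HOXB genes 2 fell after median-ratio scaling or without Parental replicate 2, 3 after quantile normalisation, and 1 without Parental replicate 1, IDH1R132H replicate 2, IDH2R140W replicate 3 or IDH2R172K replicate 1. Counts adjusted over the list alone were those over all genes.

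**Figure D3:**
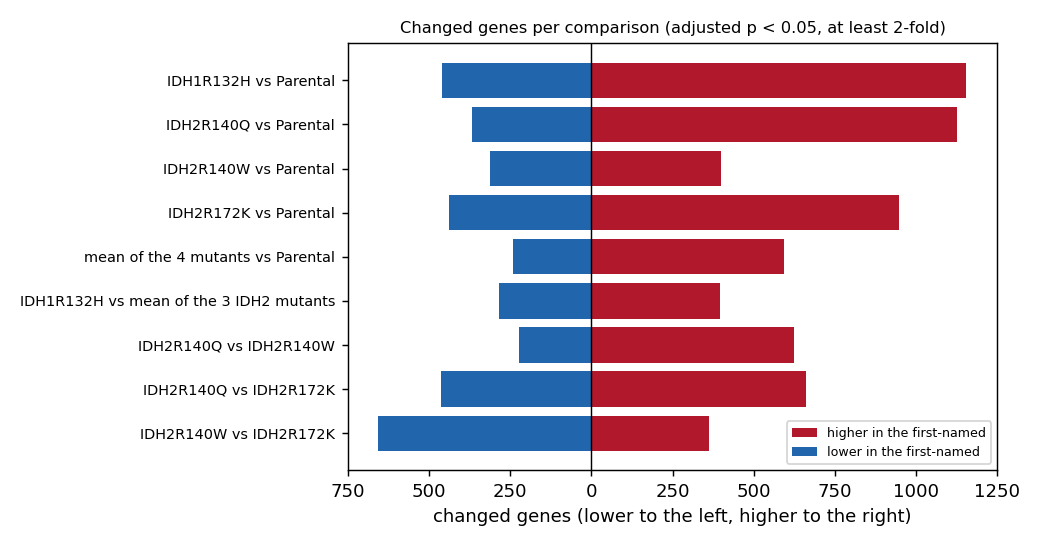
Number of genes changed by limma (adjusted p under 0.05 and at least 2-fold) in each comparison, with bars from 0 for genes higher and lower. In IDH1R132H against Parental 1152 were higher and 460 lower, and in IDH2R140W 399 and 312.

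Several lists bear on functions that 2-hydroxyglutarate, the product of mutant IDH enzymes, is known to affect, or on the metabolism around it, and some of them passed camera against Parental. Those of dioxygenases, methylation, hypoxia and homologous recombination did not pass in any mutant. The lowest adjusted p was 0.267 for 41 2-oxoglutarate dioxygenases, 0.183 for 24 genes of DNA and histone methylation, 0.567 for 26 hypoxia genes and 0.0555 for 28 genes of homologous recombination. At most 2 of the dioxygenases were higher and 1 lower in one mutant, and among the hypoxia genes at most 4 and 3. A list that does not pass is not shown to be unchanged. Transcript levels also do not measure the activity of the encoded enzymes, so these lists cannot show whether that activity was altered. Of the dioxygenases found in the data 41 of 49 were tested, and of the methylation genes 24 of 28. KDM2B, PHF8, KMT2A and EHMT2 stand on more than 1 row and were listed at 0 in every library. They could not be tested, and that value need not mean lack of expression.

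Genes of branched-chain amino acid breakdown fell as a list of 21 in IDH1R132H (camera adjusted p = 0.00247, adjusted p = 0.227 with an estimated correlation), IDH2R140W (0.00706, adjusted p = 0.213 with an estimated correlation) and IDH2R172K (0.00164, adjusted p = 0.192 with an estimated correlation). In IDH2R140Q the list fell too (0.0315, adjusted p = 0.350 with an estimated correlation), but not without Parental replicate 1 (0.0634, range 0.00365 to 0.0634). In IDH1R132H 2 members fell, also adjusted over the list alone, and in the others none. These were BCAT2, the mitochondrial transaminase, at 24.1 ± 0.401 against 49.6 ± 2.13 TPM, and HIBADH, a dehydrogenase of valine breakdown, at 7.61 ± 1.21 against 16.98 ± 1.83. BCAT2 was under 2-fold without Parental replicate 2 (−0.97) or IDH1R132H replicate 3 (−0.995184), and HIBADH without IDH1R132H replicate 3 (−0.97). Oxidative phosphorylation fell in IDH2R140Q (9.39e-07, adjusted p = 0.432 with an estimated correlation) with 1 of 49 lower, also adjusted over the list alone, and with none lower without Parental replicate 2, IDH2R140Q replicate 1 or IDH2R140Q replicate 3. It passed in IDH1R132H and IDH2R140W (0.000244 and 0.000755, with none changed alone, adjusted p = 0.635 and 0.606 with an estimated correlation), but not without Parental replicate 2 (0.0690 and 0.349, ranges 4.53e-06 to 0.0690 and 2.74e-08 to 0.349), and it did not pass in IDH2R172K (0.0735). Genes of the TCA cycle and glutamine, a list of 38 that holds IDH1 and IDH2, fell in IDH2R140W (camera adjusted p = 0.0119, adjusted p = 0.475 with an estimated correlation) and IDH2R172K (0.00854, adjusted p = 0.467 with an estimated correlation), and did not pass in IDH1R132H (0.245, 2 higher and 2 lower) or IDH2R140Q (0.930, none changed). In IDH2R140W 1 member fell, IDH1 itself, which was under 2-fold without Parental replicate 3 or IDH2R140W replicate 3. In IDH2R172K 2 fell, ME1 and SUCLA2, a subunit of succinyl-CoA synthetase (16.9 ± 1.39 against 42.8 ± 6.79 TPM), and after median-ratio scaling 4 fell. SUCLA2 lies on chromosome 13, in a run of 25 genes (42886388 to 49209779) with a median of −1.03 in IDH2R172K. These counts were the same adjusted over the list alone.

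IDH1R132H was next compared with the mean of the 3 IDH2 mutants, all grown without GM-CSF. HLA class II transcripts were lower in IDH1R132H, where CD74 stood at 39.9 ± 1.55 TPM against a mean of 447 (log2 difference −3.14, limma adjusted p = 2.33e-12) and 9 of 10 members of the list fell (median −2.62; camera adjusted p = 1.66e-14, adjusted p = 0.000299 with an estimated correlation). Amino acid response genes were higher, with 5 of 27 higher and none lower (median 0.65; 1.31e-12, adjusted p = 0.0364 with an estimated correlation). DDIT4 stood at 160 ± 2.73 against a mean of 35.4, and CHAC1, which degrades glutathione, at 19.2 ± 0.484 against 5.38. NRF2 targets were higher with 3 of 21 members (median 0.38; 2.82e-05, adjusted p = 0.0119 with an estimated correlation), which were the sulfiredoxin SRXN1 on chromosome 20, OSGIN1 and the cystine transporter SLC7A11. Of 42 interferon response genes 13 were lower and 1 higher (median −0.58; 4.18e-06, adjusted p = 0.0441 with an estimated correlation). Globins were lower with 6 of 9 members (median −1.84; 8.52e-08, adjusted p = 0.0619 with an estimated correlation), and the mitochondrially encoded list was lower with none changed alone (median −0.64; 2.62e-08, adjusted p = 0.199 with an estimated correlation), although 1 was lower without IDH2R140W replicate 3. Ribosomal protein genes were lower as a list with none changed alone (0.00388, adjusted p = 0.771 with an estimated correlation), a call lost without IDH2R140W replicate 3 (0.0507) and after quantile normalisation (0.248), within a range of 0.000425 to 0.248. Haematopoietic cytokines were lower with 4 of 12 members (0.00388, adjusted p = 0.199 with an estimated correlation), among them GM-CSF itself, CSF2 (1.35 ± 0.182 against 7.31).

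Against each IDH2 mutant alone, not all of these lists passed. Globins did not pass between IDH1R132H and IDH2R140Q (camera adjusted p = 0.604, 3 higher and 2 lower). They were lower in IDH1R132H than in IDH2R140W with 7 of 9 lower and 1 higher (2.84e-09, adjusted p = 0.0584 with an estimated correlation) and than in IDH2R172K with 7 lower (1.71e-10, adjusted p = 0.0287 with an estimated correlation). Interferon response genes did not pass against IDH2R172K (0.472, 3 higher and 5 lower). They were lower than in IDH2R140Q with 19 of 42 lower and 1 higher (1.29e-10, adjusted p = 0.0139 with an estimated correlation) and than in IDH2R140W with 7 lower and 2 higher (1.16e-05, adjusted p = 0.0584 with an estimated correlation). Haematopoietic cytokines were lower than in IDH2R140W with 6 of 12 lower and 1 higher (5.78e-05, adjusted p = 0.0957 with an estimated correlation), and did not pass against IDH2R140Q (0.240, 1 higher and 3 lower) or IDH2R172K (0.150, 2 higher and 4 lower). NRF2 targets did not pass against IDH2R140W (0.168, 3 higher and none lower). As a list they were higher than in IDH2R140Q with none of 21 changed alone (0.00262, adjusted p = 0.0425 with an estimated correlation) and than in IDH2R172K with 5 higher (9.66e-08, adjusted p = 0.00205 with an estimated correlation). Ribosomal protein genes did not pass against IDH2R172K (0.677). As a list they were lower than in IDH2R140W with 1 of 69 lower (1.2e-22, adjusted p = 0.277 with an estimated correlation) and higher than in IDH2R140Q with none changed alone (0.00073, adjusted p = 0.824 with an estimated correlation).

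The largest differences of IDH1R132H from the IDH2 mutants were higher MS4A2 (33.6 ± 0.664 TPM against a mean of 1.38) and LIN28B, an inhibitor of let-7 microRNA maturation (48.0 ± 3.41 against 4.18). HDC, at 0.623 ± 0.460 against 39.3, and KCNN4, a calcium-activated potassium channel, at 5.25 ± 1.00 against 53.6, were lower. The HDC mean includes IDH2R172K, where HDC was the largest rise against Parental, so it need not describe the other IDH2 mutants. By limma 682 genes differed, 396 higher and 286 lower (58.1% higher). Counts adjusted over the list alone were those over all genes for the lists named, and 16 of 43 lists passed by camera, 5 of them also with an estimated correlation.

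Substitutions of IDH2 at one arginine, IDH2R140Q and IDH2R140W, were compared directly. CIITA stood at 22.3 ± 1.08 TPM in IDH2R140Q and 1.76 ± 0.273 in IDH2R140W (log2 difference 3.09, limma adjusted p = 3.97e-08), CD74 at 727 ± 24.7 and 131 ± 9.33, and 8 of 10 HLA class II presentation genes were higher in IDH2R140Q (camera adjusted p = 2.21e-06, adjusted p = 0.0111 with an estimated correlation). Globins were lower in IDH2R140Q with 5 of 9 members (median −2.34; 1.7e-14, adjusted p = 0.0152 with an estimated correlation), and HBB stood at 4.76 ± 0.353 against 113 ± 18.7. Of 16 eosinophil, basophil and mast cell genes 5 were lower and 1 higher, or 8 and none after median-ratio scaling or quantile normalisation (median −0.97; 1.76e-05, adjusted p = 0.0111 with an estimated correlation), with TPSB2 at 4.64 ± 0.598 against 60.1 ± 10.4. Megakaryocyte genes were higher with 8 of 14 members (5.84e-05, adjusted p = 0.130 with an estimated correlation), and PPBP stood at 38.2 ± 0.927 against 1.497 ± 0.360. STAT5 targets were lower with 5 of 21 members (2.67e-06, adjusted p = 0.199 with an estimated correlation), among them LIF (1.68 ± 0.278 against 25.5 ± 4.65) and OSM (6.07 ± 0.800 against 36.5 ± 3.32). Cholesterol synthesis was higher with 4 of 23 members (4.82e-07, adjusted p = 0.0542 with an estimated correlation), including HMGCS1 at 166 ± 8.26 against 65.3 ± 9.40. Only 1 of the 23, HMGCS1, was higher by at least 2-fold after median-ratio scaling, and likewise after quantile normalisation, where ACAT2 stood at 0.83 and 0.93 and MSMO1 at 0.94 and 0.91. ACAT2 was also under 2-fold without IDH2R140W replicate 1 (0.99). MT1G, a metallothionein, stood at 0.573 ± 0.206 against 76.5 ± 2.78, and APOC2, an activator of lipoprotein lipase, at 0.180 ± 0.312 against 30.5 ± 6.30. By limma 847 genes differed, 624 higher and 223 lower in IDH2R140Q (73.7% higher), and after median-ratio scaling 390 and 345 (53.1% higher). These lists had the same counts adjusted over the list alone.

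IDH2R140Q was also compared with IDH2R172K. HBG2 stood at 6.07 ± 1.23 TPM in IDH2R140Q and 676 ± 62.4 in IDH2R172K (log2 difference −6.59, limma adjusted p = 1.99e-11), and 7 of 9 globins were lower in IDH2R140Q (median −2.92; camera adjusted p = 1.07e-12, adjusted p = 0.0334 with an estimated correlation). Erythroid regulators and membrane genes were lower with 8 of 27 members (0.000521, adjusted p = 0.122 with an estimated correlation). Interferon response genes were higher with 15 of 42 members (median 0.63; 3.2e-11, adjusted p = 0.0226 with an estimated correlation), and ISG15, an interferon-induced ubiquitin-like protein, stood at 113 ± 1.40 against 37.5 ± 0.674. Amino acid response genes were higher with 9 of 27 members (1.7e-08, adjusted p = 0.0979 with an estimated correlation), and PSAT1, an enzyme of serine synthesis, stood at 71.2 ± 3.03 against 25.8 ± 3.72. Of 38 genes of the TCA cycle and glutamine 7 were higher (0.00891, adjusted p = 0.554 with an estimated correlation), among them IDH2 itself (1.21, adjusted p = 8.55e-08). Monocyte and macrophage genes were lower with 5 of 17 members and 1 higher (0.000352, adjusted p = 0.164 with an estimated correlation), and the signalling adaptor TYROBP stood at 87.3 ± 5.34 against 591 ± 18.4. By limma 1126 genes differed, 662 higher and 464 lower in IDH2R140Q (58.8% higher). These lists had the same counts adjusted over the list alone.

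IDH2R140W and IDH2R172K differed in 1021 genes by limma, 363 higher and 658 lower in IDH2R140W (35.6% higher, and 45.9% after median-ratio scaling). MT1G stood at 76.5 ± 2.78 TPM in IDH2R140W and 0.683 ± 0.308 in IDH2R172K (log2 difference 5.54, adjusted p = 1.21e-10), and CSF1R, the receptor of macrophage colony-stimulating factor, at 0.877 ± 0.191 and 19.6 ± 1.21. Of 17 monocyte and macrophage genes 5 were lower in IDH2R140W (camera adjusted p = 0.00314, adjusted p = 0.324 with an estimated correlation), and of 10 HLA class II presentation genes 4 were lower (median −0.76; 0.000202, adjusted p = 0.0335 with an estimated correlation). NRF2 targets were higher as a list with 2 of 21 members higher and 1 lower (median 0.35; 0.000462, adjusted p = 0.0335 with an estimated correlation), and AKR1C1 stood at 117 ± 7.72 against 28.0 ± 3.17. Amino acid response genes were higher with 5 of 27 members (1.14e-08, adjusted p = 0.110 with an estimated correlation), and haematopoietic cytokines with 5 of 12 (0.000692, adjusted p = 0.242 with an estimated correlation), among them CSF1 at 51.1 ± 8.81 against 8.18 ± 1.60. Replication-dependent histones were lower with 5 of 26 members, or 6 adjusted over the list alone and 8 without IDH2R140W replicate 3 (0.00370, adjusted p = 0.324 with an estimated correlation), and HIST1H1C stood at 16.6 ± 3.89 against 113 ± 2.08. The libraries were poly(A)-selected, and how much of the histone transcripts that selection kept is unknown. For the other lists named here the count adjusted over the list alone was that over all genes.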

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

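The tests of symbols listed at 0, of copy number and of the globins were chosen only after the result was seen, whereas the test of GC content and length and the splits of the libraries were chosen before.

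Some gene lists moved one way in IDH1R132H and the other way in IDH2 mutants, each against Parental, and the difference between the mutants was tested directly with camera. Only lists whose direct difference passed at the preset correlation are given, so those passes were a condition of inclusion and add no support. HLA class II presentation fell in IDH1R132H and rose in the IDH2 mutants, and the rise in IDH2R140W was lost at adjusted p = 0.116 with an estimated correlation. IDH1R132H was lower than IDH2R140Q (adjusted p = 4.95e-14, 9 of 10 members lower), than IDH2R140W (1.2e-09, 6 lower) and than IDH2R172K (1.18e-13, 8 lower), and these differences held with an estimated correlation (0.000347, 0.00196 and 0.000431). The direct differences were not refitted without symbols on more than 1 row. HLA-DMA, HLA-DOA, HLA-DOB and HLA-DPA1, which stand on several rows, were listed at 0 in every library and could not be tested. The rise of that list in IDH2R140W was lost without IDH2R140W replicate 3 (0.0758, range over the alternatives 0.00276 to 0.949), and the rises in IDH2R140Q and IDH2R172K were lost without symbols on more than 1 row (0.255, range 1.04e-06 to 0.255, and 0.144, range 1.88e-07 to 0.144). The list of ATF4 and the amino acid response passed as higher in IDH1R132H and as lower in IDH2R140Q, IDH2R140W and IDH2R172K. None of these calls held with an estimated correlation (adjusted p = 0.555, 0.484, 0.338 and 0.0666 in that order). IDH1R132H was higher than IDH2R140Q (1.37e-07, 2 of 27 members higher), than IDH2R140W (1.78e-06, 7 higher) and than IDH2R172K (1.66e-15, 14 higher), with adjusted p = 0.124, 0.103 and 0.0193 with an estimated correlation. The call of that list in IDH2R140Q (0.0315) was lost without Parental replicate 1 (0.0681) and without Parental replicate 3 (0.0500479), within a range of 0.00651 to 0.0681, and there its median was 0.06 while its mean was −0.01. The mitochondrially encoded list passed as lower in IDH1R132H and as higher in IDH2R140Q, which was lost at adjusted p = 0.515 and 0.574 with an estimated correlation, and in IDH2R140Q also after median-ratio scaling (0.0656, range 0.000114 to 0.0656). The difference between these mutants passed (4.97e-10, 4 of 13 members lower in IDH1R132H, adjusted p = 0.158 with an estimated correlation).

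In 68 genes a change in one mutant was opposite to that in another. The difference between these mutants also passed in all 68. Opposite changes of at least 2-fold against the same controls all but fix that result, so it adds no support. HSH2D stood at 92.3 ± 1.497 TPM in IDH2R172K, 1.89 ± 0.794 in Parental and 0.0600 ± 0.104 in IDH1R132H. The metallothionein MT1G stood at 76.5 ± 2.78 in IDH2R140W, 7.197 ± 1.97 in Parental and 0.573 ± 0.206 in IDH2R140Q. LIN28B stood at 48.0 ± 3.41 in IDH1R132H, 10.9 ± 2.11 in Parental and 0.173 ± 0.0208 in IDH2R140W. HBBP1, a beta globin pseudogene chosen after its values were seen, stood at 82.0 ± 7.49 in IDH2R172K, 30.5 ± 2.92 in Parental and 0.710 ± 0.210 in IDH2R140Q.

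Many symbols were listed at 0 in all 15 libraries, among them GATA1, the central erythroid transcription factor, and CSF2RA and IL3RA, receptor chains for GM-CSF and interleukin 3. Lack of expression is argued against as the whole cause, since 10 of 187 members of the ribosomal protein, oxidative phosphorylation, glycolysis and TCA cycle lists were at 0, including RPL7A, RPS18, TPI1 and PGK1, which every dividing cell uses. All 10 stood on more than 1 row of the table. Of 1144 protein-coding symbols on more than 1 row 67.7% were at 0, against 7.89% of 17964 on 1 row, a ratio of 8.571, so a candidate explanation is that reads shared between copies of a gene were discarded. Which step did so is open, and the groups of the design give no explanation to set against it.

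The median of all protein-coding genes of a chromosome lay over 0.25 above or below that of all others in 5 of 92 values looked at, with chromosome 20 at 0.35 in IDH1R132H and 0.49 in IDH2R140Q, chromosome 10 at −0.41 in IDH2R140Q, and chromosomes 8 and 13 at −0.37 and −0.25 in IDH2R172K, while of the 87 smaller values, such as chromosome 20 at 0.23 in IDH2R172K and −0.10 in IDH2R140W, 31 also lay beyond random sets. In runs of 25 genes these shifts were uneven, since on chromosome 20 the run from 24949230 to 32809356 stood at −0.54 in IDH1R132H and −0.60 in IDH2R140Q, on chromosome 13 the 3 runs from 35474182 to 57729311 stood at −0.58, −1.03 and −0.84 and the others between −0.27 and 0.07, on chromosome 8 the first 5 runs stood between −0.17 and 0.09, and on chromosome 10 the first 4 stood between −0.21 and −0.01 and the others between −0.74 and −0.38. GC content or gene length is argued against as the whole cause, since after a correction for both the 5 shifts stood at 0.35, 0.50, −0.45, −0.34 and −0.24, all still beyond random gene sets. A candidate explanation is a copy-number difference of parts of these chromosomes from the parental cells, since in 5 of 5 shifts chosen on every other gene the higher-level and the lower-level genes in between both lay beyond random sets (0.31, 0.47, −0.40, −0.38 and −0.24), although both classes also did so in 13 of the 87 smaller values and single runs were not tested. RNA cannot separate copy number from joint regulation of neighbouring genes, no DNA data were used here, and an effect of the IDH genotype stays open, untested.

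Globin levels differed between mutants, with summed TPM of 2902 ± 515 in Parental, 293.8 ± 19.4 in IDH1R132H, 387 ± 0.759 in IDH2R140Q, 1017 ± 142 in IDH2R140W and 1667 ± 60.7 in IDH2R172K. The labels give the mutants the same medium without GM-CSF, and 7 of 9 globins were lower in IDH2R140Q than in IDH2R172K by limma. The sum over the genes differed by a ratio of 4.304 between these mutants. That argues against reads that only moved between near-identical globin genes as the whole cause. Had shared reads been discarded instead, the sum would not be kept, so it cannot decide that case. The genotype and the history of each edited line stay open, untested, and either might account for the differences.

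Other splits of the same libraries were fitted for each count of changed genes, and 1 split, the real one, reached the real count in every comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of only these libraries, the real split gave 1592 genes and the highest other 2 for IDH1R132H, 1470 and 1 for IDH2R140Q, 642 and 2 for IDH2R140W, and 1336 and 1 for IDH2R172K against Parental. It gave 842 and 2 for IDH2R140Q against IDH2R140W, 1127 and 2 for IDH2R140Q against IDH2R172K, and 995 and 1 for IDH2R140W against IDH2R172K. Over 100 splits each, the share was under 0.05 for the mean of the 4 mutants (835 genes, highest other 49). The same held for changes in all 4 mutants (190 and 2) and for IDH1R132H against the IDH2 mutants (682 and 97). The other splits drew single libraries at random and so mixed different lines, while each genotype was 1 group of 3 libraries. They show that libraries of a group resemble each other, and cannot exclude chance differences between lines. No group was tested for outlying libraries, since each held 3.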

How the results depend on the processing

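Leaving out symbols on more than 1 row, and leaving out Parental replicate 2 with IDH2R140W replicate 3, were chosen after seeing the data. Under every alternative that applied, 325 of 369 gene results and 105 of 154 list results kept their direction and side of the threshold. A pseudocount of 0.1 raised the changed genes in IDH2R140W from 711 to 1115, in the mean of the 4 mutants from 835 to 1608, in IDH1R132H against the IDH2 mutants from 682 to 1178, in IDH2R140Q against IDH2R140W from 847 to 1298, and in all 4 mutants from 190 to 364. Median-ratio scaling raised the IDH1 and IDH2 differences that passed from 5 to 8. For these counts the cause was not tested. Median-ratio scaling moved the number of members higher or lower by over 1.5 times in 41 of the 154 list results, quantile normalisation in 40, a pseudocount of 0.1 in 32, and the replicate block in 1. HLA class II presentation in IDH2R140W turned to lower without symbols on more than 1 row (adjusted p = 0.949, range 0.00276 to 0.949), and the cause was not tested. IDH2 in IDH1R132H, which did not pass in the main fit, lay there at −0.0146. Leaving out each library in turn, it lay between −0.0737 without IDH1R132H replicate 2 and 0.0399 without IDH1R132H replicate 3, with 0.0307 without Parental replicate 3. It lay lower after median-ratio scaling (−0.209, limma adjusted p = 0.0324), after quantile normalisation (−0.165) and with library weights (−0.108). The cause was not tested. Leaving out each library in turn gave 1454 to 1853 changed genes in IDH1R132H, 1352 to 1743 in IDH2R140Q, 696 to 814 in IDH2R140W, 1316 to 1583 in IDH2R172K, 801 to 971 in the mean and 166 to 212 in all 4 mutants. It gave 659 to 701 for IDH1R132H against the IDH2 mutants, 782 to 987 for IDH2R140Q against IDH2R140W, 1124 to 1176 for IDH2R140Q against IDH2R172K and 979 to 1103 for IDH2R140W against IDH2R172K. Without Parental replicate 2 and IDH2R140W replicate 3, whose ribosomal protein shares were high, the counts were 1461, 1361, 753 and 1329 for IDH1R132H, IDH2R140Q, IDH2R140W and IDH2R172K, 808 for the mean and 182 for all 4 mutants. Among the direct comparisons they were 675 for IDH1R132H against the IDH2 mutants, 798 for IDH2R140Q against IDH2R140W, 1139 for IDH2R140Q against IDH2R172K and 997 for IDH2R140W against IDH2R172K. The replicate numbers did not pair the libraries, since 1 of 30 pairs of deviations with the same number had r over 0.1 (−0.29 to 0.22), whereas pairs with different numbers reached 0.50. With the replicate number as a block the counts were 1610, 1493, 710 and 1383 for IDH1R132H, IDH2R140Q, IDH2R140W and IDH2R172K, 836 for the mean and 189 for all 4 mutants, all of the 369 gene results kept their call, and 1 of the 154 list results lost it, cancer-testis genes in IDH2R140Q (0.0585, range 0.0361 to 0.832). TPM keeps no depth, so how far depth limits the low genes is unknown.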

Other observations

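In this part the values of CD34, LINC00324 and the small nuclear RNAs, the number of symbols above 0, the correlation of deviations and the comparison of CYTL1 and EMC10 over all groups were chosen only after the result was seen. CD34, a surface marker of haematopoietic progenitors, stood at 153 ± 30.4 TPM in Parental and rose to 512 ± 5.36 in IDH1R132H, 485 ± 9.67 in IDH2R140Q and 533 ± 17.9 in IDH2R172K. In IDH2R140W CD34 was 276 ± 34.8, under 2-fold. GPR56, an adhesion receptor, rose from 9.76 ± 3.35 to 99.2 ± 3.33 in IDH1R132H, and MMRN1, a platelet and endothelial protein, from 5.66 ± 1.06 to 32.2 ± 1.72. Of 22 stem and progenitor genes 7 rose and 1 fell in IDH1R132H, 9 rose and 1 fell in IDH2R140Q and in IDH2R172K, and 3 rose and 1 fell in IDH2R140W, the same counts as adjusted over the list alone. By camera the list passed in IDH1R132H (adjusted p = 0.0414, range over the alternatives 0.00565 to 0.107, and adjusted p = 0.635 with an estimated correlation), and the call was lost in 4 of 18 alternatives, among them without Parental replicate 2 (0.0550). In the other mutants it did not pass (0.0844 in IDH2R140Q, 0.0701 in IDH2R140W and 0.113 in IDH2R172K).

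CYTL1 stood at 0.610 ± 0.176 TPM in IDH2R172K and between 15.6 and 32.2 in the other groups. EMC10 stood at 0.050 ± 0.0866 in IDH2R140Q and between 32.4 and 53.5 in the others. LINC00324 stood at 15.3 ± 0.232 in IDH2R172K and at most 0.520 elsewhere. Small nuclear RNAs had group means with an SD above the mean in IDH2R172K, such as RNU5E-1 at 311 ± 539 and RNU5A-1 at 272 ± 471, against at most 5.03 and 4.84 elsewhere. An SD this large over 3 libraries arises where a single library holds nearly all the signal, so these means do not describe the group. IDH2R140Q replicate 2 had 28116 symbols above 0, and the other libraries 18393 to 21267. The deviations of Parental replicate 2 and IDH2R140W replicate 3 from their group means correlated across genes at r = 0.50.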
